A study of Mus musculus with 32 samples.

How the data were processed

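RNA was measured in tibialis anterior muscle of C57BL/6J mice that were young or old, received vehicle or BI01, and had an injury by barium chloride (BaCl in the labels) or none. BI01 is described by the series as a senolytic, a compound meant to remove senescent cells. The series title names the binding of p53 to MDM2 as its target. MDM2 is a ubiquitin ligase that marks the transcription factor p53 for degradation. Per the labels, total RNA was isolated with the Qiagen miRNeasy Mini Kit, and library preparation and mRNA sequencing were done at Novogene. Processing notes in the labels name HISAT2 as the aligner and mm10 as the genome. The aligner's version, the counting tool, the annotation release and the strandedness are not given in the sources used here. The deposited table holds counts per gene and library, with Ensembl identifiers, symbols, biotypes and coordinates. The values were checked to be whole numbers. Counts of genes that overlap another gene, or that have close paralogs, are uncertain for this reason. The table lists 54532 genes in 32 columns of counts, and every column was used.

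The libraries fell into 8 groups of 4. Table columns give the group and a number that differs from the replicate number in the sample titles. Columns could be matched to groups but not single samples, and libraries are named by group and table number. Uninjured columns carry PBS (injection not stated) and the name of the 35-day set, so day 7 had no uninjured set of its own. This confounds every comparison of day 7 with uninjured muscle, and every difference of differences at day 7, with the collection set. The labels do not say that each library came from a separate animal, so p-values refer to the spread between these samples. No pair of libraries within a group had counts alike enough to be the same material.

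Total counts were 15207125 to 17634255 in young uninjured muscle, 15458439 to 17798256 in young muscle at day 7 and 15141390 to 24356966 in young muscle at day 35. They were 15404429 to 30439358 in old uninjured muscle, 14129350 to 17979203 in old vehicle muscle at day 7 and 16077532 to 19820190 in old vehicle muscle at day 35. Old muscle with BI01 had 17234091 to 21590707 counts at day 7 and 16419816 to 16886978 at day 35. With these totals and this spread, the median gene had a 95% confidence interval of ±0.58 to ±0.61 on the log2 scale in the comparisons of 2 groups.

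Counts were scaled with TMM factors in edgeR 4.0.16 (R 4.3.3). The filter filterByExpr kept 17121 genes, 14293 of them protein-coding. A quasi-likelihood model with robust dispersion was fitted to all 32 libraries with 1 mean per group. Each comparison was a contrast of group means, and p-values were adjusted by Benjamini and Hochberg over the genes tested. A gene was called at an adjusted p under 0.05, and adjusted p-values of genes are edgeR values unless another tool is named. There were 9 comparisons of 2 groups and 3 differences of differences. Expression values are CPM (counts per 1e6 counts) of the TMM-scaled library, given as mean ± SD over 4 libraries. Fold changes are on the log2 scale, with the standard error (SE) of the model. A fold against a group with no counts was computed against a floor of 3 counts over the group. Where a group had 1 to 3 counts, the ratio of shares of counts is given with an exact 95% interval. These floors and intervals cover counting error only. Fitted fold changes of such genes depend on the prior count of the model and are no bounds, so list medians were also computed with these genes at their floor.

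Lists of genes for 28 processes and cell types were written from general knowledge. With limma 3.58.1, camera compared each list with all other genes on log2 CPM (prior count 2), two-sided, with a preset correlation of 0.01 between genes. P-values were adjusted over the 28 lists within a comparison. Beside it, camera was run with a correlation estimated per list. The test fry was run too, which asks whether the genes of a list move on balance in 1 direction and compares no list with other genes. Of the 28 lists' 452 tested genes, 11 were in more than 1 list. The lists described for each comparison were chosen after the list results were seen.

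Genes were named by a rule. For a comparison of 2 groups these were the 5 largest rises and the 5 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between the 4 and 4 libraries, predicted genes left out. By chance, 2.86% of genes would show no overlap. Added were up to 4 members with the smallest p of each described list, and Cdkn1a, Cdkn2a, Mdm2 and Trp53 in the BI01 comparisons and in uninjured muscle. For differences of differences, 3 genes each way were named without the criterion on overlap. A few genes that the rule selects are not reported here. The lists, the tests, this rule and most alternatives were fixed before the data were examined, and genes named outside the rule are marked as chosen after their values were seen.

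Alternatives were DESeq2-type (RLE) factors, DESeq2 1.42.0, limma voom with sample weights, no filter on low counts, a filter of 1 CPM in 4 libraries, only the compared groups, a block for the table number, and each library left out in turn. Chosen after the data were seen were scaling by library size alone, the number of genes detected as a covariate, leaving out both old vehicle libraries numbered 7 and 10 at day 7 (which stood apart in genes detected, share of the 10 most abundant genes or share of rRNA genes), and a block for the table number within age over the uninjured and day 35 libraries. The method was tested on simulated data with 200 changed genes per comparison, built with the dispersions estimated from the compared groups. In the 12 simulations it made 0 to 7 false calls. Tables were read with the package data.table (version 1.17.8) and plots drawn with matplotlib 3.10.9 in Python 3.11.15.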

Results

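The data were RNA-seq counts from tibialis anterior muscle, a fast muscle of the shin, in 32 libraries. Young and old mice given vehicle were sampled uninjured, at day 7 and at day 35 after barium chloride injury, a chemical injury that destroys fibres and leaves stem cells to rebuild them. Old mice given BI01 were sampled at day 7 and day 35. Each of these 8 groups had 4 libraries. The first principal component held 61.1% of the variance and the second 6.49%. Muscle at day 7 needed higher scaling factors (1.06 to 1.42 in young, 1.51 to 1.87 in old) than uninjured muscle (0.67 to 0.73 in young, 0.78 to 0.83 in old). The 10 most abundant genes took 27.5% to 31.8% of the counts in young uninjured muscle and 8.02% to 15.6% in old vehicle muscle at day 7. Mitochondrial genes took 10.1% to 15.0% of the counts in young uninjured muscle, and 3.06% to 5.34% in old vehicle muscle at day 7. Changes below are relative to TMM scaling. With library size alone, the median log2 fold change of all genes moved from 0.09 to 0.29 for age in uninjured muscle. It moved from 0.17 to 1.05 for day 7 in young, from 0.14 to 1.15 for day 7 in old and from 0.13 to 0.34 for day 35 in young muscle. For age at day 7 it moved from 0.04 to 0.36, and for the difference in the day 35 response from -0.05 to -0.22.

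The series title concerns muscle of aged mice, and uninjured old muscle was first set against uninjured young muscle. Pdk4 (ENSMUSG00000019577, chromosome 6, 5483351 to 5496309), whose kinase restrains the entry of pyruvate into mitochondria, fell from 4922 ± 1805 CPM (SD, n = 4) in young to 247 ± 80.6 CPM in old muscle, 19.9-fold (log2 fold change -4.32, SE 0.65, adjusted p = 0.000133). Acot2, a mitochondrial acyl-CoA thioesterase, fell from 104 ± 34.7 to 12.6 ± 3.52 CPM (-3.05, SE 0.28, adjusted p = 5.57e-08). The ubiquitin ligase gene Trim63, which marks sarcomere proteins for degradation, fell from 2398 ± 1625 to 325 ± 75.9 CPM (-2.88, SE 0.44, adjusted p = 0.000136). Among the largest falls were also the clock gene Per1 (-2.93), the mTORC1 inhibitor gene Ddit4 (-3.13, or -2.53 without young library 3) and the arrestin-domain gene Arrdc2 (-3.18, or -4.03 without old library 9). Genes of fetal or slow fibres rose. Tnnt2 (ENSMUSG00000026414), a troponin T of heart and immature muscle, rose from 1.13 ± 0.60 to 36.9 ± 48.2 CPM (5.02, SE 1.01, adjusted p = 0.00182). Without old library 7 its log2 fold change was 3.51. Myoz2, a Z-disc protein of slow fibres, rose from 0.909 ± 0.534 to 8.49 ± 5.86 CPM (3.20, SE 0.60, adjusted p = 0.000838). Further large rises were in Zfp365 (4.41, or 3.21 without old library 7 and 5.16 without young library 1), Myom3 (3.79) and Myl4 (3.04, or 2.07 without old library 7). In each of these 11 genes all 4 libraries of an age lay beyond all 4 of the other. The naming rule required this of all except Trim63.

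**Figure D1:**
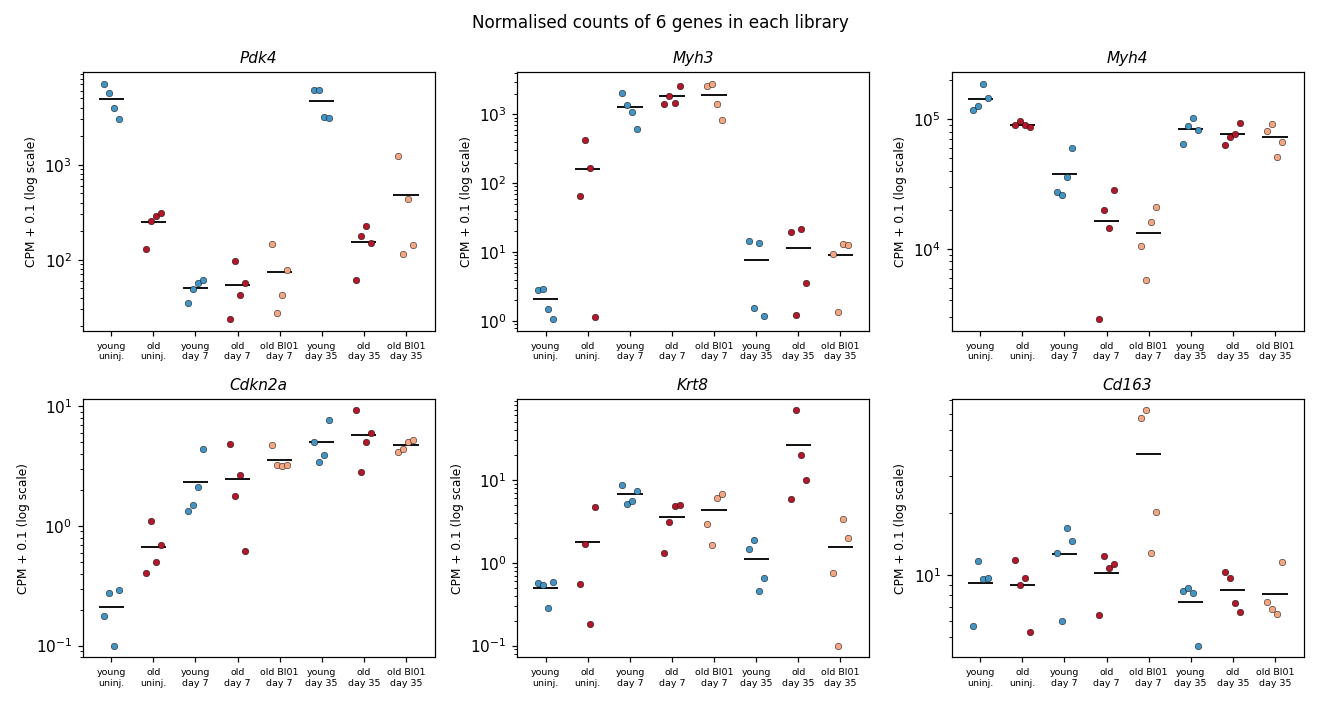
CPM plus 0.1 on a log axis for Pdk4, Myh3, Myh4, Cdkn2a, Krt8 and Cd163, with a point per library in each of the 8 groups and a line at the group mean. Pdk4 averaged 4922 CPM in young and 247 CPM in old uninjured muscle.

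By gene list, atrophy genes were lower in old uninjured muscle, with 0 of 15 called higher and 10 called lower (0 and 13 adjusted over the list alone) and a median log2 fold change of -1.13. Their camera adjusted p was 1.17e-10, and with an estimated correlation 0.0819. Besides Trim63, the autophagy gene Gabarapl1 (-1.85), the transcription factor gene Foxo3 (-1.45) and the ligase gene Fbxo21 (-0.92) fell, each in all 4 libraries. Regenerating fibre proteins were higher, with 10 of 13 called higher and 1 lower (11 and 1 adjusted over the list alone), a median of 1.90 and an adjusted p of 1.47e-05 (0.252 with an estimated correlation). They included Myh3 (ENSMUSG00000020908), the embryonic myosin heavy chain, at 164 ± 185 CPM in old and 1.98 ± 0.94 CPM in young muscle (6.35, SE 1.23, adjusted p = 0.00129). Only 3 of 4 old libraries lay above all young ones, and without old library 7 the log2 fold change was 5.27. Smooth muscle actin Acta2 rose too (2.16, adjusted p = 0.000943). Slow fibre genes had 7 of 11 called higher and 0 lower (10 and 0 adjusted over the list alone), with a median of 4.81, or 3.19 with genes without counts at their floor. Their adjusted p was 2.67e-05, and 0.196 with an estimated correlation. Casq2 (2.54, or 1.76 without old library 7) and Tnni1 (5.99, or 4.49 without old library 7 and 6.64 without young library 2) rose. Atp2a2 rose by 1.11, but without old library 7 its value was 0.53 (adjusted p = 0.108, range over its alternatives 0.000699 to 0.108). Limma voom did not call Myh3 (0.315), Tnni1 (0.445), Tnnt2 (0.175) or Myom3 (0.0929), the highest adjusted p over their alternatives, where the lowest were 1.825e-08, 2.84e-06, 5.40e-07 and 6.62e-07.

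The list of senescence and secretory genes had 4 of 29 called higher and 0 lower in old uninjured muscle (4 and 0 adjusted over the list alone), with a median of 0.96 (0.75 with floors). Its adjusted p was 0.00851, and 0.875 with an estimated correlation. Cdkn2a (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653), which encodes the cell cycle inhibitor p16 and a second protein that binds MDM2, was at 0.572 ± 0.306 CPM in old and 0.112 ± 0.091 CPM in young muscle (2.38, SE 0.78, adjusted p = 0.0393). Its 4 old libraries lay above all young ones, but the call was lost without young library 1 (0.123) or 3 (0.153) or old library 7 (0.156) or 9 (0.0603), with adjusted p from 0.0253 to 0.299 over the alternatives. The growth factor binding gene Igfbp3 (1.10, adjusted p = 0.0169) lost its call without young library 1 (0.0608) or 3 (0.0685), with 0.00709 to 0.0685 over the alternatives. Il1b, an inflammatory cytokine with no counts in young muscle, was at least 4.98-fold higher (adjusted p = 0.0299). Without young library 1 (0.0827) or 3 (0.0851) or old library 7 (0.0786) it was not called, and its alternatives gave 0.0130 to 0.0851. Vegfa, a growth factor of vessels, rose by 1.04 (adjusted p = 0.0393), and the call was lost without young libraries 1 (0.117) or 3 (0.158) or old libraries 6 (0.103), 8 (0.0683) or 9 (0.0750), over a range of 0.0127 to 0.158. Cdkn1a, Mdm2 and Trp53 were not called by edgeR. Cdkn1a was at 45.6 ± 23.6 against 27.2 ± 18.3 CPM (0.75, adjusted p = 0.246). Mdm2 was at 86.2 ± 11.4 against 96.9 ± 20.7 CPM (-0.17, or 0.03 with library size alone, adjusted p = 0.399). Limma voom called Cdkn1a (1.31, adjusted p = 0.0253, with 0.0253 to 0.691 over its alternatives). Trp53 was at 18.4 ± 3.00 against 18.5 ± 3.98 CPM (-0.01, adjusted p = 0.992), and its sign changed with library size alone (0.19) and without young library 1 (0.16) or old libraries 6 (0.09) or 9 (0.04). Neutrophil genes had 2 of 5 called higher and 0 lower (3 and 0 adjusted over the list alone), a median of 2.74 and an adjusted p of 0.00851 (0.252 with an estimated correlation). The receptor gene Csf3r rose (1.80, adjusted p = 0.00180; 0.0783 by limma voom, over a range of 0.000705 to 0.0783), as did S100a9 (adjusted p = 0.00504), with 1 count in young muscle and a ratio of 62.3 (interval 10.9 to 2487), and its fitted log2 fold change of 5.595 was 7.70 without young library 1. S100a8 was not called (3.40, adjusted p = 0.0532), but was with a filter of 1 CPM (0.0488), library size alone (0.0388) or DESeq2 (0.0263) and without old library 8 (0.0387), with 0.0263 to 0.186 over its alternatives. Mmp8 was not called (adjusted p = 0.163). Antigen presentation (median 0.89, 1 of 16 called, 5 adjusted over the list alone, adjusted p = 0.00851) and oxidative phosphorylation genes (0.48, 1 of 35 called, 0 adjusted over the list alone, adjusted p = 0.000217) were higher by camera, and with an estimated correlation these were 0.875 and 0.965.

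In the whole comparison edgeR called 2302 genes for age in uninjured muscle, 992 higher and 1310 lower in old. The share higher was 43.1%, and 78.0% with library size alone. Without young library 1 the count was 1131, without young library 3 it was 1013 and without old library 7 it was 1430. Camera called 7 of 28 lists, and none of the 7 calls held with an estimated correlation. The median of the p53 target list was -0.17 and its sign changed with library size alone (0.03, adjusted p = 0.254). For cell cycle genes the median was -0.11 while the test pointed up (adjusted p = 0.797), and with library size alone the median was 0.09.

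**Figure D2:**
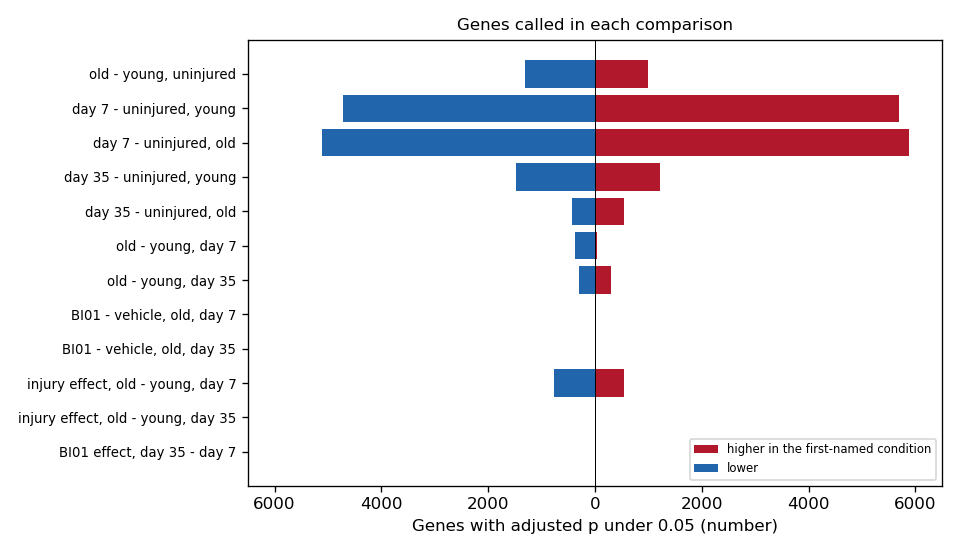
Number of genes called higher and lower by edgeR (bars, linear axis from 0) in each comparison. The day 7 comparisons with uninjured muscle had 10413 and 10995 called genes and the comparisons of BI01 with vehicle had 0.

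Young muscle at day 7 after injury was set against young uninjured muscle. Postn (ENSMUSG00000027750), a matrix protein secreted by fibroblasts, rose from 3.07 ± 1.38 to 1458 ± 534 CPM (8.90, SE 0.68, adjusted p = 1.67e-11). The collagen gene Col6a3 rose from 18.2 ± 7.26 to 733 ± 142 CPM (5.33, SE 0.38, adjusted p = 1.83e-12), beside Bgn (4.93) and Fap (3.43), which mark matrix and activated fibroblasts. Actc1, the actin of heart and immature muscle, rose from 45.2 ± 19.4 to 3044 ± 851 CPM (6.07, SE 0.48, adjusted p = 1.13e-11), and Ncam1 (4.88), Acta2 (4.52) and Nes (3.21) rose with it. The macrophage receptor gene Csf1r rose from 9.89 ± 5.21 to 168 ± 44.7 CPM (4.09, SE 0.50, adjusted p = 5.93e-08). Stem cell genes Megf10 (4.67), Vcam1 (3.36), Heyl (2.68) and Myf5 (2.44) rose as well. In all of these genes the 4 injured libraries lay above the 4 uninjured ones, and no call was lost with any library left out. Genes of dividing cells and macrophages depended on young uninjured library 2 for their size. Without it the log2 fold change went from 5.91 to 7.58 for Top2a, 5.14 to 6.92 for Mki67, 4.99 to 5.80 for Kif11, 5.86 to 6.67 for Cx3cr1, 4.51 to 6.03 for Fcgr1 and 4.41 to 5.35 for Adgre1, while Mcm6 stayed near 3.65.

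The largest rises in young muscle at day 7 were in genes without counts in uninjured muscle. Fbn2, a fibrillin of developing matrix, was at 20.1 ± 7.64 CPM, at least 304-fold higher (adjusted p = 8.71e-09). By the same floor Mmp13 was at least 188-fold, Dcx at least 158-fold, St8sia2 at least 119-fold and Agtr2 at least 115.0-fold higher. The fitted value of Mmp13 was 10.19 without day 7 library 5, and fitted values of such genes depend on the prior count. Among the falls, Slc15a5 (ENSMUSG00000044378), of a family of peptide transporters, went from 13.2 ± 4.31 CPM to no counts, at least 384-fold lower (adjusted p = 8.95e-08), and Exph5 was at least 163-fold lower. Odf3l2 fell from 19.2 ± 3.81 to 0.0655 ± 0.0757 CPM (-8.00, SE 0.68, adjusted p = 4.21e-11). Cyp4f39 (-7.10, or -8.05 without day 7 library 7) and Rasd2 (-6.80, or -8.01 without the same library) fell too.

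EdgeR called 10413 genes for day 7 in young muscle, 5698 higher and 4715 lower, and 9741 to 10452 with a library left out. Uninjured libraries belonged to the 35-day set, so these counts include any difference between collection sets. The share higher was 54.7%, or 87.3% with library size alone. Camera called 19 of 28 lists with the preset correlation and 0 with an estimated one, where adjusted p-values of these 19 were 0.234 to 0.626. All 26 matrix genes were called higher (26 adjusted over the list alone; median 4.26, adjusted p = 8.68e-14). Cell cycle genes had 25 of 27 higher and 0 lower (25 and 0; 3.65, 2.51e-07), macrophage genes 19 of 20 and 0 (19 and 0; 4.03, 5.58e-07) and regenerating fibre proteins 12 of 13 and 0 (12 and 0; 4.88, 4.91e-06). Satellite cell genes had 11 of 15 higher and 2 lower (11 and 2; 2.44, 0.00213). Interferon genes had 24 of 24 higher (24; 2.48, 6.94e-07), antigen presentation 16 of 16 (16; 2.66, 3.61e-06), senescence and secretory genes 23 of 29 (23; 3.36, 2.99 with floors, 4.91e-06) and T and NK cells 13 of 15 (14; 5.18, 3.84 with floors, 0.00213), with 0 lower in each. Also called higher as lists were slow fibre genes with 8 of 11 higher and 1 lower (9 and 1; 5.39, 5.26 with floors, 0.00388) and fibro-adipogenic progenitors with 7 of 14 and 0 (7 and 0; 0.88, 0.0158). Neuromuscular junction genes had 13 of 18 higher and 3 lower (13 and 3; 1.30, 0.0114) and complement 10 of 15 and 1 (10 and 1; 1.86, 0.0168). Called lower were atrophy genes with 0 of 15 higher and 13 lower (0 and 13; -1.92, 3.29e-06), glycolysis with 1 of 20 and 12 (1 and 12; -1.06, 0.00361), mature fast fibre genes with 1 of 16 and 10 (1 and 10; -1.62, 0.0190), clock genes with 1 of 15 and 7 (1 and 7; -0.99, 0.0165) and p53 targets with 7 of 25 and 13 (7 and 13; -0.93, 0.0471). Oxidative phosphorylation genes had 0 of 35 higher and 12 lower (0 and 9; -0.49, 0.00699), but with library size alone the median was 0.36.

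Other lists were not called for day 7 in young muscle. Tenocyte genes had 6 of 10 higher and 0 lower (6 and 0 adjusted over the list alone; median 1.93, adjusted p = 0.0712) and erythroid genes 0 of 7 and 4 (0 and 4; -2.50, 0.0712). Neutrophil genes had 3 of 5 higher and 0 lower (3 and 0; 3.46, 0.155), smooth muscle 4 of 12 and 2 (4 and 2; 0.61, 0.283) and immediate early genes 8 of 18 and 3 (8 and 3; 0.61, 0.290). By fry, which asks for a shift of the list itself, all of these had adjusted p from 2.88e-06 to 0.0148. Lists of Schwann, endothelial, adipocyte, and B and plasma cells were called neither by camera (0.675 to 0.750) nor by fry.

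In old muscle given vehicle, genes of energy metabolism fell at day 7. Fbp2, a fructose bisphosphatase of muscle, fell from 49.3 ± 4.76 to 1.87 ± 0.846 CPM (-4.74, SE 0.40, adjusted p = 7.78e-11), and the glycolysis genes Pkm (-2.06), Phka1 (-3.72) and Aldoa (-3.49) fell too. The fast troponin gene Tnnt3 fell from 19100 ± 1039 to 2512 ± 1441 CPM (-2.93, SE 0.37, adjusted p = 4.86e-08), with Tnni2 (-3.03), Ckm (-2.98) and Mybpc2 (-3.69). Respiratory complex genes Ndufb5 (-1.96), Ndufa4 (-2.20) and Ndufb8 (-1.90) fell as well. Genes of the interferon response rose, such as the antiviral gene Oasl2 from 3.67 ± 1.60 to 51.8 ± 10.8 CPM (3.79, SE 0.35, adjusted p = 1.60e-10), Ddx58 (2.94), Ifit2 (3.02) and Stat2 (2.17). In each of these genes the 4 injured libraries lay beyond the 4 uninjured ones, and every call held with each library left out.

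Among the largest rises in old muscle at day 7, Ltbp2, which binds latent TGF-beta in matrix, went from 0.153 ± 0.114 to 92.0 ± 41.9 CPM (8.98, SE 0.69, adjusted p = 1.86e-11; 9.69 without uninjured library 7). Tnc rose from 1.57 ± 1.56 to 546 ± 514 CPM (8.44, or 7.56 without day 7 library 7). Tnn, a tenascin, had 1 count in uninjured muscle and a ratio of 2323 (interval 417 to 91800). By the same measure Kif2c, with 1 count, had a ratio of 573.0 (103 to 22660) and Ccnb1, with 3 counts, a ratio of 357 (122 to 1733), both genes of cell division. Without day 7 library 7 the fitted log2 fold changes of Tnn, Kif2c and Ccnb1 were 9.41, 7.88 and 7.55. They were 12.11 without uninjured library 8 for Tnn, and 10.08 and 10.98 without uninjured library 7 for Kif2c and Ccnb1. Slc15a5 had no counts at day 7 and was at least 642-fold lower than in uninjured muscle (18.8 ± 3.82 CPM). Odf3l2, with 1 count at day 7, was lower by a ratio of 1267 (227 to 50110), with a fitted value of -10.89 without day 7 library 9. Ostn (-8.62), Kcng4 (-8.53) and Tmem132b (-7.63) fell, and without day 7 library 9 these values were -11.41, -11.72 and -8.88.

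For day 7 in old muscle edgeR called 10995 genes, 5885 higher and 5110 lower, and 10234 to 10901 with a library left out. The share higher was 53.5%, and 86.0% with library size alone. Camera called 16 of 28 lists, and 0 with an estimated correlation. Oxidative phosphorylation had 0 of 35 genes called higher and 35 lower (0 and 35 adjusted over the list alone), a median of -1.56 and an adjusted p of 1.40e-10 (0.323 with an estimated correlation). Glycolysis and glycogen genes had 1 of 20 higher and 18 lower (1 and 18 adjusted over the list alone; median -2.21, adjusted p = 1.96e-07, and 0.302 with an estimated correlation). Mature fast fibre genes had 0 of 16 higher and 13 lower (0 and 13; -2.45, 4.58e-05, and 0.323 with an estimated correlation). All 24 interferon genes were called higher (24; 2.53, 1.31e-07, and 0.302 with an estimated correlation). The p53 target list had a positive median (0.35), a negative mean (-0.06) and a test that pointed down (adjusted p = 0.319). Atrophy genes had a median of -0.80, which was 0.23 with library size alone (adjusted p = 0.0222, and 0.430 with an estimated correlation).

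Both ages shared much of the day 7 response. Across 17121 genes, which are not independent replicates, the log2 fold changes of old and young muscle correlated with r = 0.84 (Spearman 0.85). Called in both ages were 4649 genes higher (1959 by chance) and 3684 lower (1407 by chance), and 79 were called in opposite directions. The difference between the ages was tested as a difference of differences, in which 1319 genes passed, 552 higher and 767 lower in old relative to young. The share higher was 41.9%, with 55.2% by RLE factors and 54.0% with library size alone. This count was 587 without young uninjured library 1, 573 without young uninjured library 3, 801 and 852 without old uninjured libraries 6 and 8, 740 without young day 7 library 7 and 2152 without old day 7 library 9. Pdk4 led the positive differences (4.42, SE 0.84, adjusted p = 0.00328), with a fall from 247 ± 80.6 to 54.4 ± 30.7 CPM in old and from 4922 ± 1805 to 50.55 ± 11.55 CPM in young muscle. Shroom3 (ENSMUSG00000029381), which shapes the actin of epithelia, had a difference of 3.97 (adjusted p = 0.00544, with 7.19e-05 to 0.0599 over its alternatives; 3.23 without young uninjured library 3). Ddit4 had a difference of 3.84 (adjusted p = 0.00544; 3.25 without the same library). Negative differences were in Myh3 (-5.84, adjusted p = 0.0186) and St8sia2 (-6.89, adjusted p = 0.0211), for which the young uninjured group had no counts, so that the value depends on the prior count. Myh3 was at 1845 ± 550.5 CPM in old and 1294 ± 611 CPM in young muscle at day 7. It was not called without young uninjured library 3 (0.0527) or old uninjured library 7 (-4.76, 0.0505), with 0.00114 to 0.430 over its alternatives. St8sia2 was not called without young uninjured library 1 (0.0585) or 3 (0.0566), and was -5.93 without old uninjured library 7, with 0.00137 to 0.0771 over its alternatives.

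Tnni1, a slow troponin gene, had a difference of -5.82 (adjusted p = 0.0299). It lost its call with 6 of 16 libraries left out (0.0506 to 0.0981, and 0.00364 to 0.472 over all alternatives). These were young uninjured libraries 1 and 3, old uninjured 7 (-4.32), young day 7 library 7 and old day 7 libraries 7 and 10. Without young uninjured library 2 the difference was -6.48. By list, oxidative phosphorylation had 0 of 35 called higher and 13 lower (0 and 33 adjusted over the list alone; median -1.14, adjusted p = 7.98e-16, and 0.563 with an estimated correlation). Glycolysis genes had 0 of 20 higher and 7 lower (0 and 13; -1.05, 1.10e-08, and 0.563), and fast fibre genes 0 of 16 and 1 (0 and 8; -1.22, 8.05e-05, and 0.702). Regenerating fibre proteins had 0 of 13 higher and 6 lower (0 and 9; -1.66, 0.000894, and 0.563) and slow fibre genes 0 of 11 and 4 (0 and 10; -5.02, 0.000894, and 0.563). Atrophy genes had 6 of 15 higher and 0 lower (10 and 0; 1.15, 1.03e-06, and 0.508).

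Young muscle at day 35 was compared with uninjured young muscle. Mdfi, which inhibits myogenic transcription factors, rose from 1.53 ± 0.861 to 14.3 ± 6.50 CPM (3.20, SE 0.40, adjusted p = 3.75e-06), and the kinase gene Map3k9 rose from 0.746 ± 0.307 to 5.14 ± 1.24 CPM (2.80, SE 0.38, adjusted p = 1.01e-05). Musk (ENSMUSG00000057280), the receptor kinase that organises the neuromuscular junction, fell from 67.5 ± 61.0 to 4.95 ± 2.69 CPM (-3.75, SE 0.53, adjusted p = 2.74e-05; -3.16 without uninjured library 3). Matrix genes rose, as in Mmp2 (ENSMUSG00000031740), a collagenase, from 25.0 ± 6.37 to 61.6 ± 14.7 CPM (1.30, SE 0.28, adjusted p = 0.00191), Col3a1 (1.72, adjusted p = 0.00666) and Sparc (1.03, adjusted p = 0.00864). The actin-severing gene Gsn rose from 280 ± 53.2 to 740 ± 116 CPM (1.40, SE 0.27, adjusted p = 0.000737). In these genes all 4 libraries of a group lay beyond the 4 of the other. The naming rule required this of Mdfi, Map3k9 and Musk. Further rises were in Cyfip2 (3.76), Sln (3.69, or 4.57 without uninjured library 4) and Col24a1 (3.42, or 5.02 without uninjured library 4 and 2.43 without day 35 library 4). Further falls were in Elf3 (-4.96), Htra4 (-4.37, or -3.74 without uninjured library 1) and Pkdrej (-3.93), and Exph5, with 3 counts at day 35, was lower by a ratio of 114 (38.4 to 554), with a fitted value of -9.71 without day 35 library 2.

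For day 35 in young muscle edgeR called 2691 genes, 1209 higher and 1482 lower, with 1660 without young uninjured library 1 and 1309 without young uninjured library 3. The share higher was 44.9%, and 78.6% with library size alone. Camera called 5 of 28 lists, and 0 with an estimated correlation. The matrix list had 13 of 26 called higher and 1 lower (19 and 1 adjusted over the list alone; median 1.08, adjusted p = 5.61e-06, and 0.894 with an estimated correlation). The member called lower was Loxl1 (-1.31, adjusted p = 0.00479, with 0.000233 to 0.102 over its alternatives), with 2 of 4 libraries below all uninjured ones. Fibro-adipogenic progenitor genes had 6 of 14 higher and 0 lower (9 and 0; 0.87, 0.00398, and 0.894). Of these Cd34 (1.05, adjusted p = 0.00889) was not called without uninjured library 3 (0.0559, over a range of 0.00278 to 0.0559), Dpt (1.14) not without uninjured library 1 (0.0527) or 3 (0.0644; 0.00223 to 0.0666), and Hic1 (0.92) not without day 35 library 1 (0.0643) or uninjured library 3 (0.0691; 0.00468 to 0.244). Oxidative phosphorylation genes had 5 of 35 higher and 0 lower (5 and 0; 0.56, 5.61e-06, and 0.894). Their calls rested on young uninjured libraries 1 and 3. Without them Sdhd (0.95) had adjusted p of 0.0639 and 0.0882 (range 0.00131 to 0.0882) and Ndufb8 (0.84) had 0.0748 and 0.102 (0.00216 to 0.102). In the same way Ndufa5 (0.87) had 0.0953 and 0.136, with 0.110 without day 35 library 4 (0.00198 to 0.136). Ndufa1 (1.39, 3 of 4 libraries above) had 0.0895 and 0.132, with 0.0507 and 0.201 without day 35 libraries 1 and 4 (0.00101 to 0.201).

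Neuromuscular junction genes at day 35 in young muscle had 3 of 18 called higher and 6 lower (4 and 6 adjusted over the list alone), with a positive median (0.18), a negative mean (-0.13) and a test that pointed down (adjusted p = 0.817). Hdac4, a deacetylase that responds to loss of nerve supply, was called lower (-1.58, adjusted p = 0.0102), but its groups overlapped, and without uninjured libraries 1 and 3 its adjusted p was 0.0530 and 0.103 (0.000496 to 0.506 over its alternatives). Lrp4, the receptor of nerve-derived agrin, rose by 0.87 (adjusted p = 0.0176, 3 of 4 libraries above), and was not called without uninjured library 1 (0.0690) or day 35 library 3 (0.0867; range 0.000710 to 0.0867).

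Old vehicle muscle was examined at day 35 too. Cdkn2a rose from 0.572 ± 0.306 CPM in uninjured to 5.67 ± 2.68 CPM in injured old muscle (3.22, SE 0.52, adjusted p = 0.000199), with the 4 injured libraries above all uninjured ones by the naming rule, and kept its call with each library left out. Mmp2 rose from 19.5 ± 5.88 to 80.9 ± 4.96 CPM (2.05, SE 0.29, adjusted p = 2.64e-05) and the basement membrane collagen Col4a1 from 75.4 ± 11.3 to 285 ± 53.4 CPM (1.92, SE 0.27, adjusted p = 3.04e-05), beside Col4a2 (1.58) and Sparc (1.64). Genes of fibro-adipogenic progenitors rose, with Cd34 from 22.1 ± 6.34 to 61.5 ± 12.9 CPM (1.48, SE 0.27, adjusted p = 0.00104), Pdgfra (1.15), Dpt (1.51) and Gsn (1.30). Dkk3, a secreted protein of the Wnt field, fell from 55.2 ± 32.9 to 2.28 ± 0.373 CPM (-4.60, SE 0.41, adjusted p = 2.49e-08). Other large falls were in Rasd2 (-5.21), Tmem132b (-5.06), Syt9 (-4.31, or -5.11 without day 35 library 8) and Bdh1 (-4.04). Krt8 (ENSMUSG00000049382), a keratin of simple epithelia, rose from 1.67 ± 2.03 to 26.1 ± 28.9 CPM (3.87, adjusted p = 0.00450, with 0.0003195 to 0.0729 over its alternatives; 2.75 without day 35 library 7 and 5.01 without uninjured library 9). Apln (2.78), which encodes a peptide hormone, and B3galt2 (2.32) rose too. Sln rose by 2.77, and was not called without uninjured libraries 6 (0.0652) or 8 (0.0734) or day 35 library 7 (0.0597; 0.000536 to 0.0734 over its alternatives).

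EdgeR called 966 genes for day 35 in old muscle, 543 higher and 423 lower, and 556, 635 and 616 without old uninjured library 8, old uninjured library 9 and old day 35 library 7. Camera called 9 of 28 lists, and 0 with an estimated correlation. The matrix list had 15 of 26 called higher and 0 lower (18 and 0 adjusted over the list alone; median 1.25, adjusted p = 2.54e-18, and 0.256 with an estimated correlation). Fibro-adipogenic progenitor genes had 7 of 14 higher and 0 lower (10 and 0; 1.23, 5.96e-09, and 0.282). The p53 target list had 1 of 25 called higher and 3 lower (1 and 5; -0.31, 0.00937, and 0.256). Of its members Dglucy fell (-0.86, adjusted p = 0.00507). The repair polymerase gene Polk fell by 0.84 on the log2 scale, with adjusted p of 0.0564 to 0.142 without any of old uninjured libraries 8 and 9 and day 35 libraries 6, 7 and 8. Rrm2b fell by 0.58, with 0.0520 to 0.0690 without any of uninjured libraries 6 and 9 and day 35 libraries 6 and 9. Trp53inp1 rose by 0.63, with 0.0519 to 0.124 without any of uninjured libraries 6, 7 and 9 and day 35 libraries 7, 8 and 9. Over all their alternatives these 3 genes had adjusted p of 0.000204 to 0.142, 1.38e-05 to 0.0690 and 0.00298 to 0.124. Senescence and secretory genes had 4 of 29 higher and 0 lower (4 and 0; 0.39, 0.0637), namely Cdkn2a and 3 binding proteins of insulin-like growth factors. Of these Igfbp7 (1.15) was not called without uninjured library 8 (0.0545) or day 35 library 8 (0.0531), with 7.32e-06 to 0.0555 over its alternatives. Igfbp3 (1.01) lost its call without any library except day 35 library 8 (0.0550 to 0.161; 0.000326 to 0.161 over its alternatives). Igfbp4 (0.93) lost it without any of uninjured libraries 7, 8 and 9 and day 35 libraries 7, 8 and 9 (0.0663 to 0.166; 0.000613 to 0.166 over its alternatives).

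At day 35 the responses of the ages correlated with r = 0.35 (Spearman 0.42) across genes, which are not independent replicates, and with r = 0.598 among genes of at least 5 CPM. Called in both were 281 genes higher (38.3 by chance) and 287 lower (36.6 by chance), and 0 in opposite directions. In the test of the difference itself edgeR called 0 genes (1690 at an unadjusted p under 0.05, smallest adjusted p = 0.0609). DESeq2 called 47 genes and limma voom 4. A block for table numbers within age, over uninjured and day 35 libraries, called 5 (Myo1e higher and Tspan8, Armh4, Col24a1 and Hcn4 lower in old, named after their values were seen). Leaving out young uninjured library 4 gave 40 genes, young uninjured library 2 gave 1, young day 35 library 1 gave 2 and old uninjured library 9 gave 2. In simulated data of this test, 35.8% of 2-fold and 80.3% of 4-fold changes were recovered. Camera called 4 lists here. Slow fibre (median -2.41) and oxidative phosphorylation genes (-0.37) had an adjusted p of 0.00321 each, matrix genes 0.0110 (median 0.44) and regenerating fibre proteins 0.0311 (median -1.18). With an estimated correlation all were at 0.992.

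Old and young muscle were compared at day 7. Gpi1 (ENSMUSG00000036427), an enzyme of glycolysis, was at 452 ± 87.2 CPM in old and 869 ± 225 CPM in young muscle (-0.94, SE 0.18, adjusted p = 0.00624). Plin4, a coat protein of lipid droplets, was at 16.2 ± 9.51 against 87.2 ± 46.9 CPM (-2.43, SE 0.47, adjusted p = 0.00906). The carbonic anhydrase gene Car14 (-2.65, or -3.50 without old library 9), the tubulin gene Tuba8 (-2.52), the transporter gene Slc47a1 (-2.39, or -3.01 without old library 9), Fbp2 (-1.98), Ldha (-1.15) and Pkm (-0.89) were lower, in all 4 old libraries for each gene. The naming rule required this of Plin4, Car14, Tuba8 and Slc47a1. None of these calls held without young library 7, where adjusted p was 0.0638 for Gpi1, 0.0754 for Plin4, 0.0540 for Car14, Tuba8, Slc47a1 and Fbp2, 0.200 for Ldha and 0.206 for Pkm. Without old library 7 Fbp2 (0.0631), Ldha (0.109) and Pkm (0.0793) were not called either. Over their alternatives adjusted p ran from 5.75e-06 to 0.366 for Gpi1, 0.000153 to 0.309 for Plin4, 5.93e-06 to 0.313 for Car14 and 0.000284 to 0.386 for Pkm. It ran from 9.16e-07 to 0.309 for Tuba8, 5.90e-06 to 0.309 for Slc47a1, 4.43e-05 to 0.293 for Fbp2 and 0.00170 to 0.366 for Ldha.

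The chemokine gene Ccl7 at day 7 was at 15.6 ± 15.0 CPM in old and 3.41 ± 1.69 CPM in young muscle (2.18, SE 0.53, adjusted p = 0.0278), and its value was 1.25 (adjusted p = 0.262) without old library 7. It was not called without young libraries 6 (0.0758) or 7 (0.182) either, with 0.0107 to 0.323 over its alternatives. Oasl1 (1.83), Cd72 (1.73), Npl (1.34) and Trim30d (1.15) were called higher, in all 4 old libraries by the naming rule. Their calls were lost without young library 7 (0.201, 0.259, 0.182 and 0.200 in this order) and without old library 7 (0.0828, 0.224, 0.128 and 0.0898). Without old library 8 they were at 0.0504, 0.0631, 0.0646 and 0.0928. Without young library 6, Oasl1 (0.0730), Cd72 (0.131) and Trim30d (0.0905) were lost, as were Cd72 without young library 5 (0.0529) and Trim30d without young library 4 (0.0689). Over their alternatives the highest adjusted p was 0.309 for Oasl1, 0.355 for Cd72, 0.342 for Npl and 0.309 for Trim30d, and the lowest was 0.00317, 0.00582, 0.00102 and 0.000938.

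EdgeR called 416 genes for age at day 7, 43 higher and 373 lower in old. The share higher was 10.3%, with 13.2% by RLE factors, 85.7% with library size alone, 22.7% by DESeq2 and 34.4% by limma voom. The count rested on single libraries, with 7 genes without young library 7, 35 without old library 7, 198 without young library 6 and 200 without old library 8. It was 630 without young library 4, 1012 without old library 9, 662 without old library 10 and 2 without both old libraries 7 and 10. Genes of the rRNA biotype took 0.0424% of the counts of old library 10, against 0.518% to 1.54% in all other libraries, and it had the fewest genes with a count at day 7 (17910). Camera called 9 of 28 lists, and 0 with an estimated correlation. Glycolysis and glycogen genes had 0 of 20 called higher and 11 lower (0 and 17 adjusted over the list alone; median -1.05, adjusted p = 6.46e-16, and 0.358 with an estimated correlation). Oxidative phosphorylation genes had 0 of 35 higher and 2 lower (0 and 22; -0.67, 2.66e-15, and 0.495). Its called members were Uqcrc1 (-0.92, adjusted p = 0.0407) and Cycs (-1.03, adjusted p = 0.0437), each below all young libraries in 3 of 4 old ones. Their calls were lost without old libraries 7 (0.176 and 0.201), 8 (0.0759 and 0.106) or 10 (0.0557 and 0.0667) or young libraries 6 (0.0881 and 0.0725) or 7 (0.271 and 0.303). Over their alternatives they ran from 0.00566 to 0.426 and from 0.00239 to 0.455. Interferon genes had 0 of 24 higher and 0 lower (1 and 0; 0.71, 5.53e-06, and 0.495) and antigen presentation 0 of 16 and 0 (2 and 0; 0.68, 1.56e-05, and 0.495). Also higher by camera were macrophage (0.74, 0.00447), T and NK cell (0.93, 0.00306) and senescence and secretory genes (0.80, 0.00198), with 0, 0 and 1 members called (Ccl7), and with an estimated correlation at 0.701, 0.495 and 0.495. Mature fast fibre genes had 0 of 16 higher and 2 lower (0 and 12; -1.08, 1.75e-09, and 0.495). Cell cycle genes had 0 of 27 higher and 0 lower (0 and 0; 0.51, 0.0223, and 0.760). Of the interferon and antigen presentation members, those nearest to a call were Ifit2 (0.93, adjusted p = 0.0515) and H2-K1 (0.77, adjusted p = 0.0788), each with 3 of 4 old libraries above. Ifit2 was called without young library 4 (0.0403) or 5 (0.0456), with library size alone (0.0301), with genes detected as a covariate (0.0487), by DESeq2 (0.01795) and by limma voom (0.000355), over a range of 0.000355 to 0.342. H2-K1 was called without old library 10 (0.0373), with library size alone (0.0361) and by DESeq2 (0.0243), over a range of 0.0243 to 0.383. Limma voom also called Stat2, Mx1, Ifi44 and Tap2.

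Age was compared again at day 35. Pdk4 was lower in old muscle, at 153 ± 69.6 against 4642 ± 1726 CPM in young, 30.3-fold (-4.92, SE 0.67, adjusted p = 5.03e-05). Tfrc (ENSMUSG00000022797), the transferrin receptor that takes up iron, was higher at 415 ± 111 against 41.9 ± 8.61 CPM (3.31, SE 0.44, adjusted p = 2.75e-05). The ligase gene Fbxo32 was lower at 315 ± 74.1 against 1430 ± 517 CPM (-2.18, SE 0.46, adjusted p = 0.00471), as were Trim63 (-1.99), Gabarapl1 (-1.74) and Fbxo21 (-1.23). Clock genes moved both ways, with Nr1d1 higher at 168 ± 14.3 against 49.5 ± 15.3 CPM (1.76, SE 0.35, adjusted p = 0.00334) and Clock higher (1.06), and Per2 (-1.98) and Cry2 (-1.02) lower. Krt8 was higher (4.65, adjusted p = 0.00217; 3.52 without old library 7), with Apln (3.26). Further falls were in Slc25a34 (-3.99), Arrdc2 (-3.90, or -4.53 without old library 9), Slc25a25 (-3.64, or -2.94 without young library 3) and Ddit4 (-3.46). In these genes the 4 libraries of an age lay beyond the 4 of the other. The naming rule required this except of atrophy and clock genes. No call was lost with a library left out. Krt18, the partner of Krt8, was higher (3.29, adjusted p = 0.0349), but was not called without old library 7 (2.27, 0.200) or 8 (0.0563) or any young library (0.0826 to 0.114), with 0.00186 to 0.200 over its alternatives.

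EdgeR called 601 genes for age at day 35, 295 higher and 306 lower in old, and 377 and 330 without young libraries 1 and 2 and 375 and 367 without old libraries 7 and 8. Called at day 35 and uninjured were 133 genes higher, 209 lower and 0 in opposite directions. Chance gives 17.1 and 23.4 if mice are separate, which stays open. Camera called 14 of 28 lists. Atrophy genes had 0 of 15 higher and 8 lower (0 and 10 adjusted over the list alone; median -0.98, adjusted p = 1.84e-12), and theirs was the single list call of the 12 comparisons that held with an estimated correlation (0.0420). Neuromuscular junction genes had 2 of 18 higher and 0 lower (6 and 0; 0.58, 0.000340, and 0.234 with an estimated correlation). Lrp4 rose by 0.88 (adjusted p = 0.0348), with 0.0749 to 0.155 without any of young libraries 1, 2 and 4 and old libraries 6 and 9 (0.00249 to 0.155 over its alternatives). Colq, which anchors acetylcholinesterase, rose by 1.17 (adjusted p = 0.0398), and lost its call without any library except old library 8 (0.0515 to 0.231; 0.00307 to 0.231 over its alternatives). Chrna1 was not called (1.26, adjusted p = 0.0758), but was without old library 9 (0.0499), with only the compared groups (0.0352), by DESeq2 (0.0163) and by limma voom (0.01003), over a range of 0.01003 to 0.288. Sln was not called (1.91, adjusted p = 0.129) except by limma voom (0.00273), with 0.341 at most. The clock list had 3 of 15 higher and 3 lower (5 and 5; -0.21, 0.758), and matrix genes 2 of 26 and 0 (3 and 0; 0.52, 0.000289, and 0.632 with an estimated correlation).

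BI01 was compared with vehicle in old injured muscle. At day 7 Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), the p53 target gene of the inhibitor p21, was at 180 ± 83.5 CPM with BI01 and 168 ± 45.5 CPM with vehicle (0.10, SE 0.41, adjusted p = 0.978). Its sign changed without BI01 libraries 1 (-0.14) or 2 (-0.07) or vehicle library 10 (-0.04). Mdm2 (ENSMUSG00000020184), also a p53 target, was at 47.5 ± 4.93 against 43.7 ± 4.32 CPM (0.12, SE 0.12, adjusted p = 0.870). Trp53 (ENSMUSG00000059552) was at 34.9 ± 3.26 against 32.1 ± 10.6 CPM (0.12, SE 0.17, adjusted p = 0.916). Cdkn2a was at 3.49 ± 0.745 against 2.36 ± 1.77 CPM (0.55, SE 0.45, adjusted p = 0.822), and limma voom called it (0.89, 0.0465, with 0.0465 to 1 over its alternatives). The macrophage receptor gene Cd163 (ENSMUSG00000008845), which takes up haemoglobin, was at 38.0 ± 25.3 against 10.1 ± 2.59 CPM (1.91, SE 0.38, adjusted p = 0.370), with all 4 BI01 libraries above all vehicle ones. It was called without vehicle library 9 (0.0458), without BI01 library 3 (0.00846) and by DESeq2 (0.0169), with 0.00846 to 1 over its alternatives.

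For BI01 at day 7 edgeR called 0 genes, with 1126 at an unadjusted p under 0.05. DESeq2 called 1, Cd163, and limma voom with sample weights called 4684. That fit gave vehicle library 8 a weight of 3.64 and BI01 library 3 one of 3.49, and 0.162 to 0.886 to the other 6 libraries of these groups. Without vehicle library 9 edgeR called 54 genes, and without BI01 library 3 it called 1, again Cd163. In simulated data of this comparison 1.49% of 1.5-fold, 23.9% of 2-fold and 84.8% of 4-fold changes were recovered. Camera called 6 of 28 lists, none with an estimated correlation, where adjusted p was 0.980 for all lists. Oxidative phosphorylation genes had 0 of 35 called (0 adjusted over the list alone), a median of 0.47 and an adjusted p of 1.93e-11. Its first members by p were Ndufb8 (0.62), Atp5d (0.55) and Uqcrfs1 (0.74), none of them called by edgeR except Uqcrfs1 without vehicle library 9 (0.0490). Cell cycle genes had 0 of 27 called (0; -0.45, 0.00238), among them Tpx2 (-0.70), Aurka (-0.64), Ccnb1 (-0.86) and Ccnb2 (-0.74). Matrix genes had 0 of 26 called (0; -0.36, 0.00466), among them Loxl2 (-0.98), Thbs1 (-1.08), Col6a3 (-0.54) and Col12a1 (-0.96). Without vehicle libraries 7 and 10 Tpx2 (0.0793), Loxl2 (0.0675) and Thbs1 (0.00201) changed sign. Of these members limma voom called Ndufb8 (0.000421), Atp5d (0.00718), Uqcrfs1 (0.000659), Tpx2 (0.00614), Ccnb1 (0.00254), Thbs1 (0.00510) and Col12a1 (0.00324), each the lowest adjusted p over the gene's alternatives, where the highest was 1.

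The remaining called lists for BI01 at day 7 were erythroid genes (0 of 7 called, 0 adjusted over the list alone, median 1.51, adjusted p = 0.0257), complement (0 of 15, 0; 0.45, 0.0268) and mature fast fibre genes (0 of 16, 0; 0.28, 0.0499). The p53 target list had 0 of 25 called (0; 0.02, 0.895), and its median changed sign with RLE factors (-0.003) and library size alone (-0.04). Its first members were Zmat3 (-0.40), Phlda3 (0.64), Ei24 (0.21) and Perp, which was at 0.175 ± 0.090 against 0.0351 ± 0.0460 CPM. Senescence and secretory genes had 0 of 29 called (0; adjusted p = 0.855), with a median of -0.02, a mean of 0.03 and a test that pointed up. Their first members were Mmp3 (1.17), Ccl8 (0.97) and Igfbp7 (0.37). Macrophage genes had 0 of 20 called (1 adjusted over the list alone, Cd163; median 0.12, adjusted p = 0.531), with C1qc at 0.43, C1qa at 0.40 and Cx3cr1 at -0.35. In these lists limma voom called Zmat3 (-0.65, adjusted p = 0.000339), Phlda3 (0.91, 0.00316), Ei24 (0.27, 0.0232), Ccl8 (1.89, 0.000174), Igfbp7 (1.21, 0.000219) and Cx3cr1 (-1.39, 0.000566), each the lowest over its alternatives, where the highest was 1.

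At day 35 the 4 target genes were lower with BI01 by amounts that did not pass the test. Cdkn1a was at 34.5 ± 14.1 against 42.4 ± 6.97 CPM (-0.30, SE 0.41), Cdkn2a at 4.62 ± 0.531 against 5.67 ± 2.68 CPM (-0.29, SE 0.45, or 0.04 without vehicle library 6), Mdm2 at 63.8 ± 2.89 against 72.2 ± 1.23 CPM (-0.18, SE 0.12) and Trp53 at 14.5 ± 1.51 against 16.3 ± 1.18 CPM (-0.16, SE 0.18). Each of these had an adjusted p of 1. Genes of the neuromuscular junction were lower by their fitted values, with Colq at 7.09 ± 1.43 against 16.2 ± 6.57 CPM (-1.19, SE 0.33, adjusted p = 0.808), below all vehicle libraries in 4 of 4. Chrnd (-1.17, 4 of 4) and Chrna1 (-1.003, 3 of 4), subunits of the acetylcholine receptor, and Dok7 (-0.29, 3 of 4) had adjusted p of 1. Clock genes Per2 (9.36 ± 3.94 against 3.84 ± 1.22 CPM, 1.29, adjusted p = 0.489) and Ciart (1.81, adjusted p = 0.854) and also Per3 (0.88) were above all vehicle libraries in 3 of 4, and Cry1 (-0.57) below in 3 of 4.

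EdgeR called 0 genes for BI01 at day 35, with 530 at an unadjusted p under 0.05, a smallest adjusted p of 0.142, and 0 with each library left out. DESeq2 called 12, namely Rbm33 and Lrch1 higher and Aif1l, Sh3d19, Cpne2, Rrad, Krt18, Hpgd, Cxcl10, Krt8, Ggt6 and Myl2 lower. Limma voom called 2, Rbm33 and Clca3a1. In simulated data of this comparison 56.7% of 2-fold and 95.5% of 4-fold changes were recovered. Camera called 5 of 28 lists and 0 with an estimated correlation. Neuromuscular junction genes had 0 of 18 called higher or lower (0 and 1 adjusted over the list alone, Colq; median -0.47, adjusted p = 0.000148, and 0.235 with an estimated correlation). Clock genes had 0 of 15 called (5 and 1 adjusted over the list alone; 0.21, 0.0463, and 0.975). Fibro-adipogenic progenitors (0 of 14, 0 adjusted over the list alone; -0.22, 0.0149), regenerating fibre proteins (0 of 13, 0; -0.41, 0.0153) and erythroid genes (0 of 7, 0; -1.21, 0.0153) were also called lower, and were at 0.975 with an estimated correlation. The p53 target list (0 of 25, 0; 0.02, 0.760) and the senescence and secretory list (0 of 29, 0; 0.02, 0.692) were not called. Their first members were Zmat3 (-0.33), Eda2r (-0.64), Cdkn2b (-0.63) and Cxcl1 (1.37), and genes near the floor, none called. Gdf15 had 1 count with vehicle and a ratio of 16.7 (2.59 to 700.0), Pmaip1 had 2 counts and a ratio of 8.35 (1.96 to 74.8), and Ccl4, without counts with vehicle, was at least 1.73-fold higher with BI01. These values ignore spread between libraries.

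The BI01 effect was also compared between day 35 and day 7. EdgeR called 0 genes (825 at an unadjusted p under 0.05, smallest adjusted p = 0.282) and DESeq2 0, while limma voom with sample weights called 1474. With any library left out edgeR called 0. In simulated data of this test 20.9% of 2-fold and 72.7% of 4-fold changes were recovered. Camera called 5 lists. These were oxidative phosphorylation (median -0.51, adjusted p = 2.22e-08), erythroid (-2.75, 0.000833), neuromuscular junction (-0.54, 0.00291), cell cycle (0.63, 0.00505) and fibro-adipogenic progenitor genes (-0.43, 0.00516), with 0 members called in each (0 or 1 adjusted over the list alone). With an estimated correlation neuromuscular junction genes were at 0.903 and the other 4 lists at 0.949. Across genes, which are not independent replicates, the effect of BI01 correlated with the effect of youth (young minus old vehicle) with r = 0.41 at day 7 and r = 0.47 at day 35. Both effects contain the same old vehicle libraries, and simulated groups without any effect gave r = 0.50 at each day for this reason. With the old vehicle libraries divided between both effects, r was -0.25 to 0.14 over the 6 divisions at day 7 and 0.09 to 0.14 at day 35. Among genes of at least 5 CPM it was -0.35 to 0.33 and 0.18 to 0.32. The covariance of both effects was 0.103 at day 7 (0.102 to 0.113 in simulations) and 0.0931 at day 35 (0.0501 to 0.0576), and among genes of at least 5 CPM 0.0492 (0.0389 to 0.0463) and 0.0482 (0.0214 to 0.0275). When BI01 and vehicle libraries were relabeled, with young muscle set against all old muscle of the day, the exact p of the covariance was 0.80 at day 7 and 0.229 at day 35, or 0.886 and 0.314 among genes of at least 5 CPM.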

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

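In this part, the tests of clock phase, of the macrophage and endothelial scores, of Myh7 and of single libraries in uninjured old muscle were chosen only after the result was seen. A library lay far from the other 3 of its group in 40 of 484 groups tested (8.26%), where chance gives about 1 in 20. This rule takes the gap to the nearest other library as a share of the group's range. Of these, 39 were CPM values of named genes, and 1 was the total count of BI01 day 7 library 2 (21590707, others 17234091 to 17857723).

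In uninjured muscle these were, in old library 9, Arrdc2 (36.9, others 8.002 to 9.99) and Gabarapl1 (52.5, others 34.8 to 37.6). In old library 8 they were Fbp2 (42.25, others 50.8 to 52.2) and Tnn (0.0800, others 0). In old library 7 they were Oasl2 (6.05, others 2.75 to 3.12), Ifit2 (6.33, others 2.64 to 2.97), Kif2c (0.0398, others 0) and Ccnb1 (0.119, others 0). In young muscle they were S100a9 in library 1 (0.0773, others 0), Fcgr1 (2.05, others 0.0965 to 0.309) and Ncam1 (3.115, others 4.82 to 5.10) in library 2, Gsn in library 3 (200.2, others 303 to 311) and Col24a1 in library 4 (9.745, others 0.851 to 1.25).

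At day 7 young library 7 stood apart in Cyp4f39 (1.10, others 0.158 to 0.254), Actc1 (4319, others 2579 to 2675), B2m (170.2, others 225 to 236) and Tnni1 (180.3, others 234 to 245), and young library 6 in Ifi44 (1.89, others 4.15 to 4.24). Old vehicle library 7 stood apart in Ccl7 (37.9, others 6.11 to 11.01), Trp53 (48.0, others 25.7 to 27.6), Thbs1 (401, others 71.7 to 126) and Ccnb2 (23.05, others 5.36 to 7.16). Old vehicle library 9 did in Odf3l2 (0.0439, others 0), Ostn (0.175, others 0) and Kcng4 (0.702, others 0 to 0.0322), and BI01 library 1 in Cdkn2a (4.61, others 3.08 to 3.15).

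At day 35 young library 2 stood apart in Sln (4.15, others 12.5 to 14.1) and Exph5 (0.160, others 0), and young library 4 in Col24a1 (84.1, others 16.1 to 18.4) and Mdfi (24.1, others 10.5 to 11.9). Among old vehicle libraries it was library 7 in Colq (26.0, others 12.4 to 13.3), Trim63 (321.5, others 206 to 222) and Dkk3 (1.72, others 2.41 to 2.51). It was library 8 in Tmem132b (1.69, others 0.699 to 0.810) and Syt9 (0.914, others 0.184 to 0.254), library 9 in Dglucy (29.6, others 23.2 to 23.8) and Gdf15 (0.0810, others 0), and library 6 in Cxcl1 (0.318, others 0.0614 to 0.0810). With BI01, library 6 stood apart in Zmat3 (10.6, others 13.1 to 13.6). Old vehicle day 7 library 7, old uninjured library 7 and young day 7 library 7 had 4 of these values each.

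For the difference in day 7 response 1319 genes passed. The log2 differences of the named genes were 4.42 for Pdk4, 3.97 for Shroom3, 3.845 for Ddit4, -6.885 for St8sia2, -5.84 for Myh3 and -5.82 for Tnni1.

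Called genes were also counted with the libraries divided into other groups of 4, or regrouped within the differences of differences. For 6 comparisons only the real grouping reached its count, 1 of 35, the lowest share possible, which cannot exclude chance. The highest counts of other groupings were 596 for age in uninjured muscle (2302 real), 3739 and 1364 for day 7 in young (10413) and old muscle (10995), 348 and 17 for day 35 in young (2691) and old muscle (966) and 1 for age at day 35 (601). For age at day 7, 3 of 35 reached 416, with 903 at most, so chance stays open. For the difference in day 7 response 2 of 40 reached 1319, with 1751 at most. Regroupings of the differences between ages mixed ages within a condition, and the highest kept the old injured libraries together, so they carried effects of age and say nothing on chance. Where the real count was 0, all 35 or 40 groupings reached it. Their highest counts were 1711 for BI01 at day 7, 3 for BI01 at day 35, 2954 for the difference in day 35 response and 139 for the BI01 effect between days. The 1711 came from old vehicle libraries 7, 8 and 10 with BI01 library 2 against the rest, largely the treatment grouping.

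The first pattern weighed was the lower Pdk4, Ddit4 and atrophy genes in old muscle, uninjured and at day 35. A list of 22 other genes of fasting and glucocorticoid response had medians of -0.99 and -1.04, with 21 of 22 below 0 in each, and -0.08 at day 7, so a fasting or glucocorticoid state of the young mice may account for it. Time of day stays open. In uninjured muscle 0 of 4 phase markers (Arntl, Npas2, Dbp, Nr1d1) were called, but this was left open after the result was seen, because Per1 (-2.93, adjusted p = 0.00336), Per2 (-0.89, 0.0495), Cry1 (0.79, 0.00604) and Cry2 (-1.22, 0.000984) were called there. An effect of age itself stays open as well and was not tested.

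The second pattern was the lower fibre metabolism genes in old muscle at day 7. A single library as the cause of the fold is argued against by the glycolysis median (-1.05), which was at most -0.81 with any library left out, although called members went from 11 to 0 without young library 7 and to 1 without old library 7. The number of genes detected is argued against by a median of -1.03 with it as a covariate. A lower share of fibre RNA could also contribute and stays open, since macrophage minus endothelial scores differed by 0.97 with an exact two-sided permutation p of 0.0571 (smallest possible 0.0286). Chance (3 of 35 groupings) stays open too, and an effect of age was not tested apart from these.

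The third pattern was the higher slow and regenerating fibre genes in old uninjured muscle. Slow muscle carried over at dissection is argued against by Myh7, the main slow myosin, at a mean of 0.21 CPM (0 to 0.839). A single library is argued against for the list, since at least 9 of 13 regenerating fibre genes stayed above 1 with any old library left out, although calls went from 10 to 6, and from 7 to 4 in the slow list, without old library 7. Of 8 fetal genes outside the list 5 were above 1 and 4 were called, but 3 and 1 without old library 7, so regenerating fibres as a source stay open. Myh3 was at 66.3, 422, 165 and 1.04 CPM in old libraries 6 to 9. An effect of PBS was not tested.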

How the results depend on the processing

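In this part, library size alone, the number of genes detected as a covariate, the fit without old vehicle day 7 libraries 7 and 10, the block for table numbers within age, and the restriction to genes of at least 5 CPM were chosen only after results were seen. With a library left out, 1737 values of named genes kept direction and call, 137 lost a call, 15 gained one and 7 changed sign. In the other settings these numbers were 1911, 97, 43 and 8. RLE factors kept 228 of 231, a filter of 1 CPM in 4 libraries 229 of 230, DESeq2 222 of 230 and limma voom 188 of 231. The cause of the changes below was not tested unless stated.

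With libraries left out singly, counts ran from 1013 to 2850 for age in uninjured muscle, 7 to 1012 for age at day 7, 330 to 442 for age at day 35, 1309 to 3103 for day 35 in young and 556 to 885 in old muscle. They ran from 573 to 2152 for the difference in the day 7 response, 0 to 40 for that at day 35 and 0 to 54 for BI01 at day 7. The log2 fold change of Trp53 age uninjured, that is old against young uninjured muscle, ran from -0.0886 to 0.157, Cdkn2a for BI01 at day 35 from -0.528 to 0.0405, and Cdkn1a for BI01 at day 7 from -0.14 to 0.30. Counts of both day 7 injury comparisons, of BI01 at day 35 and of the BI01 effect between days stayed on their side of 1.5-fold.

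Without a filter on low counts, where more genes are tested, the counts were 1524 for age in uninjured muscle, 171 for age at day 7, 817 for the difference in the day 7 response and 1 at day 35, and Trp53 in uninjured muscle was at 0.015. With library size alone age at day 7 had 712 called genes, the difference in the day 35 response 2, and in uninjured muscle Mdm2 was at 0.0283 and Trp53 at 0.19. With genes detected as a covariate the difference in the day 35 response had 2.

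DESeq2 called 850 genes for age at day 7, 921 for age at day 35, 1 for BI01 at day 7, 12 for BI01 at day 35, and 2020 and 47 for the differences in the day 7 and day 35 response. Limma voom called 3087 for day 35 in old muscle, 1881 and 2465 for age at day 7 and day 35, 4684 and 2 for BI01 at day 7 and day 35, 4 for the difference in the day 35 response and 1474 for the BI01 effect between days. It put Trp53 in uninjured muscle at 0.15 and Cdkn1a for BI01 at day 7 at -0.50.

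With only the compared groups in the fit, and so fewer libraries for the dispersion, counts were 1411 for age in uninjured muscle, 0 and 1950 for age at day 7 and day 35, 2600 for day 35 in old muscle, and 173 and 1 for the differences in the day 7 and day 35 response. A block for table numbers within age, fitted to uninjured and day 35 libraries alone (14064 genes), gave 4113 and 1602 for day 35 in young and old muscle and 5 for their difference. A block over all libraries gave 2725, 910 and 0. Libraries of the same number had 39 correlations of -0.18 to 0.16, and whether they are pairs stays open. No paired analysis was made for age at any time, day 7 in young muscle, BI01 at day 7, the difference in the day 7 response or the BI01 effect between days, because at least 1 pair of the groups compared shares fewer than 2 table numbers. Without old vehicle day 7 libraries 7 and 10, age at day 7 had 2 called genes and the difference in the day 7 response 343. For BI01 at day 7 Loxl2 was then at 0.0675, Thbs1 at 0.00201 and Tpx2 at 0.0793, all negative with these libraries.

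Of 105 list calls by camera with the preset correlation, 1 held with an estimated correlation, and fry called 68 lists, 54 of them among the 105. The correlation of the day 7 injury response between the ages rose from 0.84 to 0.899 among genes of at least 5 CPM, because genes with few counts were left out. With 4 libraries per group, simulated 1.5-fold changes were recovered in 1.49% for BI01 at day 7 and age at day 7 and in 31.3% for BI01 at day 35.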

Other observations

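In this part, the test of a shift of old muscle toward young by BI01 was chosen only after the result was seen. It used the covariance of the BI01 effect with the difference between young muscle and all old muscle of the same day. All 70 relabelings of BI01 and vehicle were compared (two-sided, exact, smallest p possible 0.0286). The p was 0.229 at day 35 and 0.80 at day 7. No shift toward young muscle was shown, and a smaller one cannot be told from the spread between 4 libraries.

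Values per library were chosen after they were seen. Krt8 at day 35 was at 5.84, 68.5, 19.9 and 9.96 CPM with vehicle and 0.647, 0, 3.28 and 1.865 CPM with BI01. Krt18 was at 15.6, 163, 46.2 and 34.9 CPM with vehicle and 2.59, 3.21, 3.68 and 4.02 CPM with BI01. Cd163 at day 7 was at 57.3, 62.0, 12.7 and 19.97 CPM with BI01 and 6.35, 12.2, 10.7 and 11.2 CPM with vehicle.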
